A study of Sus scrofa with 50 samples.

How the data were processed

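Tissue RNA from Korean minipigs (Sus scrofa) of the ET type and the L type was measured by RNA sequencing in backfat, brain, loin, lymph and tenderloin, the tissue names being those of the labels. The labels give 5 ET animals (S0235, S0242, S0276, S0309 and S0326) and 5 L animals (S0349, S0355, S0377, S0384 and S0385), each sampled in all 5 tissues, which makes 50 libraries in 10 groups of 5. The animals are named by their label numbers throughout, and ET and L are used as labels because the sources used here do not spell them out. Total RNA was extracted with TRIzol and made into stranded mRNA libraries, per the labels' protocols.

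The deposited values are TPM (length-normalised transcript shares) of 57085 assembled transcripts in each library, and every column sums to the same total. Reads were trimmed with Trimmomatic 0.36 and transcripts were quantified with Salmon 1.10.0, per the submitters' processing notes, which also name a pig genome build; what that build was used for is not given in the sources used here. The transcript names carry the tissue and type of the assembly they came from, with 20 assemblies of 10 tissues, and 33986 of the transcripts came from L assemblies and 23099 from ET assemblies. TPM keeps no depth, so the number of reads behind each library is unknown, and no counting interval can be given. The precision of each comparison comes from the spread between animals alone.

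A gene is here a Swiss-Prot protein entry. Each transcript was given the entry of its best BLASTX hit in the deposited annotation table where the E value was at most 1e-10, and the TPM of transcripts with the same entry were summed. This used 32120 transcripts and gave 14394 genes. Hits with a larger E value (1864), to repeat or retroviral proteins (2481) and to proteins from outside animals (19) were left out, as were transcripts with no hit, so that 24965 transcripts entered no comparison. Swiss-Prot entries are often those of another species, with a median identity of 92.8% to the used transcripts, so a gene name stands for the closest described protein. Members of near-identical families (haemoglobins, histones, immunoglobulins, major histocompatibility genes, myosin heavy chains) can be divided between entries and are uncertain. No reference genome was used here, so no chromosome positions are given.

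Comparisons used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with an intensity trend in the moderated variance, two-sided tests and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Genes with a mean TPM of at least 1 over the libraries of the fit were tested. A log2 fold change on this scale understates the change of genes near the pseudocount of 1. Each tissue's ET and L comparison used its own 10 libraries; the comparison of the types over tissues used 1 mean per animal; the dependence of the type difference on tissue was an F test of the interaction with the animal as a fixed block; loin against tenderloin used 20 libraries with the type as a term. A gene was called enriched in a tissue when its mean lay at least 2 log2 units above each other tissue, with every contrast called. Numbers of genes detected (TPM of at least 1) and the percent of TPM in the 10 most abundant genes were compared by two-sided exact permutation tests, adjusted over the 5 tissues.

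Gene lists for 35 pathways and cell types, with 838 distinct genes of which 714 were matched, were written before the data were examined. Lists with at least 5 genes tested were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. The design, the lists, the alternatives listed as planned and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 12 called genes with the largest change in each direction among those with a mean TPM of at least 5 in the higher group, up to 4 called members of each list by smallest p, the 10 interaction genes with the smallest p, and the 5 most abundant enriched genes per tissue. Where fewer than 5 genes pass in a direction, the 5 with the smallest p are given as values. Some list members that the rule takes in backfat, loin and loin against tenderloin are left unnamed, and some genes that the rule takes are not reported here.

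The same animals gave all tissues, so the animal number pairs libraries across tissues. Deviations from the group means correlated between loin and tenderloin libraries of the same animal with a median r of 0.36 across genes (range 0.20 to 0.61, 9 pairs), against -0.10 between different animals (36 pairs). These pairs leave out the libraries that stood apart. Over all pairs of tissues the medians were 0.12 (84 pairs) and -0.05 (320 pairs). Each group mean includes the library itself, which pushes the values between different animals towards negative ones, so they are not an independent baseline. As a check of the animal labels, each library was compared with the other libraries of every animal over 67 to 75 transcripts that were on (TPM of at least 1) in all tissues of some animals and off (TPM below 0.1) in all tissues of the others. All 50 libraries agreed best with their labelled animal, at 95.7% or more, and with no other animal above 79.4%. No pair of replicate libraries in a group held the same values.

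Alternatives were a pseudocount of 0.1, no filter or a minimum mean TPM of 5, scaling of each library by its median ratio to the geometric mean over genes with a TPM of at least 5 in every library, the most abundant transcript of a gene in place of the sum, all 50 libraries in 1 fit with the animal as a random block, library weights, a replicate block, and leaving out each animal in turn. After the libraries had been examined, 5 that stood apart from their labelled tissue were left out in added alternatives. Each comparison was tested on simulated TPM drawn from the genes' own means and spreads of log2(TPM + 1), with the types made equal first. The 5 doubted libraries were left out of these means and spreads. The recoveries below thus describe data without such libraries, while the main fits keep them. Each library was also drawn on its own, with no deviation shared by the tissues of 1 animal, unlike the real libraries. For the mean over tissues the same change was put in all 5 tissues. Its recovery can therefore be higher than in the real data. The changed genes, 100 per fold size (99 in lymph), were drawn among genes with a mean TPM of at least 10. Of genes changed by 1 log2 unit, 33% were recovered in backfat, 47% in brain, 70% in loin, 64.6% in lymph, 58% in tenderloin, 97% in the mean over tissues and 88% between loin and tenderloin; of those changed by 2 units, 86%, 92%, 91%, 91.9%, 90%, 99% and 100%. For the interaction, 42% and 89% of genes changed in backfat were recovered. Unchanged genes that were called numbered 5 to 10 in backfat, brain, loin, lymph and the mean over tissues. There were 19 in tenderloin and 21 between loin and tenderloin. The interaction called 64 unchanged genes beside 42 and 89 recovered, so more of its calls were false than an adjusted p under 0.05 allows. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and the R packages statmod 1.5.0 and, at version 1.17.8, data.table.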

Results

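RNA levels were measured in 5 tissues of 10 Korean minipigs, 5 of the ET type and 5 of the L type, to describe how the types differ. Each library held TPM for the same set of assembled transcripts, summed here to 14394 genes named by their closest Swiss-Prot protein. Between 10150 and 13157 genes reached a TPM of at least 1 per library. The 10 most abundant genes took 9.97% to 35.9% of the TPM, and transcripts without a usable protein match took 7.11% to 19.8%. Read depth is unknown.

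Each tissue held genes that were higher in it than in every other tissue. Backfat was led by FABP4, the fatty acid-binding protein of adipocytes, at 5153 ± 3772 TPM (SD, n = 10) against at most 1079 in the mean of another tissue (45.9 without the 5 libraries described next), and by GSN, DCN, SPARC and COL3A1. Brain was led by the precursor of pituitary peptide hormones POMC (16819 ± 22990 TPM, n = 10), by NNAT, PRL (prolactin, 12652 ± 14021) and CGA (the shared subunit of pituitary glycoprotein hormones, 10917 ± 10415), and by the glial gene S100B. In the brain libraries other than those of S0235 and S0355, POMC was at 5271 to 77972 TPM and CGA at 2085 to 28265. The same 8 libraries had the myelin gene MBP at 15.98 to 80.1 TPM, against 37.2 to 55.5 in lymph without S0235, and the astrocyte gene GFAP at 0.985 to 43.6. The labels say only brain and name no region. Pituitary hormone transcripts at these levels, with MBP near its lymph level, argue against myelin-rich brain tissue in these 8 libraries. Tissue mostly of the pituitary is a candidate, which was not tested. Lymph was led by the immunoglobulin light chain IGK, by SLA-DQA1, SLA-DRA and LAC, and by CCL21, a chemokine of lymph nodes (2207 ± 1196 TPM, against at most 22.6 in the mean of another tissue). Loin was led by the fast myosin MYH4 (12253 ± 7029 TPM), IGFN1, MYH8, MICAL2 and SHISA2, and tenderloin by the slow-muscle light chains MYL2 (24144 ± 12750 TPM) and MYL3 with CRYAB, CSRP3 and ANKRD2. With a replicate block MYL2 (adjusted p = 0.118) and MYL3 (adjusted p = 0.0782) did not pass as enriched. With limma, 173 genes were enriched in backfat, 1104 in brain, 8 in loin, 619 in lymph and 23 in tenderloin. Without the 5 libraries described next these counts were 240, 1257, 17, 682 and 15. S100B in brain and CRYAB in tenderloin then lay less than 2 log2 units above another tissue, by 1.24 and 1.95.

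In 46 of the 50 libraries the profile correlated best with that of the labelled tissue. Across genes, r with the labelled tissue was 0.61 to 0.97 in 45 libraries, and the other 5 stood apart. The backfat library of S0355 held muscle transcripts, with CKM, the muscle creatine kinase, at 23749 TPM against 0.0954 to 97.9 in the other backfat libraries, and its r with the backfat profile was -0.46. The loin library of the same animal held adipocyte transcripts, with ADIPOQ (adiponectin) at 1139 TPM and CKM at 0.638, and its r with the loin profile was -0.46. The lymph library of S0235 had CD3E, a subunit of the T-cell receptor complex, at 3.13 TPM against 406 to 750 in the other lymph libraries, and UMOD, a kidney tubule protein, at 2156 TPM against 0.477 to 4.61. The brain libraries of S0235 and S0355 had MBP at 30538 and 37999 TPM against 15.98 to 80.1 in the other brain libraries, and PRL at 11.09 and 13.98 against 805 to 40120. Their r with the brain profile was 0.46 and 0.49. The loin library of S0235 correlated slightly better with tenderloin (0.90) than with loin (0.88), and was kept. All libraries stay under their labels below, and values without these 5 are given beside named results whose calls they change.

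**Figure D1:**
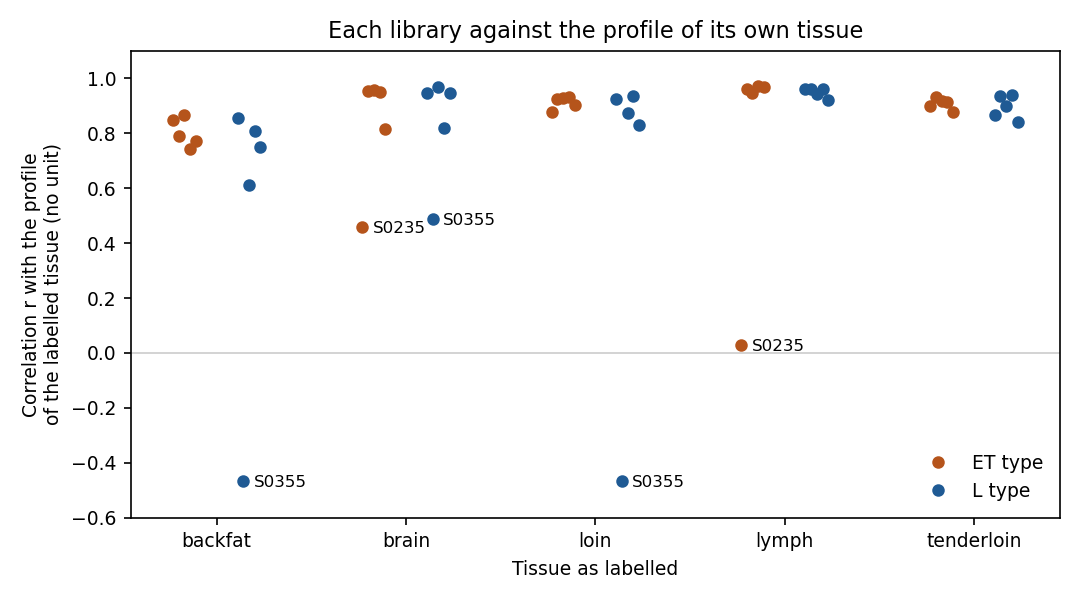
Pearson correlation across genes (y axis, no unit) of each library with the median profile of its labelled tissue (x axis), the library itself left out; each point is 1 library, coloured by type. The points of 45 libraries lie between 0.61 and 0.97, and the named libraries of S0235 and S0355 lie lower, down to -0.46.

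In backfat, genes of fat storage and lipid synthesis were far higher in ET than in L animals. SCD, the desaturase that makes monounsaturated fatty acids, was at 782 ± 1298 TPM in ET and 1.83 ± 2.15 in L (SD, n = 5 each; log2 fold change 6.67, SE 1.05, adjusted p = 0.00758). The ET mean rested on S0326 at 3087 TPM, the other 4 ET libraries lay at 21.1 to 396, and the log2 fold change was 5.75 without S0326 (adjusted p = 0.0254) and 7.53 without S0276. The satiety hormone gene LEP was at 106 ± 99.0 against 0.0105 ± 0.0144 TPM, the elongase ELOVL6 at 474 ± 332 against 7.74 ± 8.06, and the hormone-sensitive lipase LIPE at 870 ± 304 against 49.9 ± 55.5 (log2 fold change 4.54, SE 0.56, adjusted p = 0.00609). THRSP, SDR16C5, DGAT2, TUSC5, ALDOC, BCAM, CIDEC, PLIN1 and CYP4B1 completed the genes with the largest differences, at log2 fold changes of 5.09 to 6.63. Without the library of S0355 THRSP was at 6.01, TUSC5 at 4.83, ALDOC at 4.59, CIDEC at 4.49 and PLIN1 at 4.20. Without S0349 THRSP was at 7.69, DGAT2 at 6.48, TUSC5 at 6.32, CIDEC at 5.79 and PLIN1 at 5.74. Without S0276 THRSP was at 7.31, DGAT2 at 6.56 and ELOVL6 at 6.33, without S0309 LEP was at 6.69 and CYP4B1 at 5.89, and without S0377 BCAM was at 4.58. All of these values passed. SCD did not pass with 1 transcript per gene (4.90, adjusted p = 0.0861). In all, 573 genes were higher and 1 was lower in ET of 12233 tested. The lower gene was the splicing factor LUC7L3 (-1.21, SE 0.31, adjusted p = 0.0478), which lost its call in most alternatives. With all libraries the lower values next to the threshold did not pass, at -2.48 for GALNT15 (adjusted p = 0.0615), -1.29 for BEND5 (0.0617), -0.94 for INO80C (0.0708) and -1.42 for HCN2 (0.0741). GALNT15 (-2.84, adjusted p = 0.0245) and INO80C (-0.76, adjusted p = 0.0492) passed as lower without the library of S0355.

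The lipid lists moved together in backfat. Of 18 adipocyte genes, 11 were higher over all genes tested and 17 adjusted over the list alone, among them PLIN1, LGALS12, LPL (356 ± 214 against 32.3 ± 12.8 TPM) and LEP (fry adjusted p = 0.00456; camera adjusted p = 1.23e-11, but adjusted p = 0.283 with an estimated correlation). Of 22 genes of fatty acid and triglyceride synthesis, 11 were higher, and 19 adjusted over the list alone, including ELOVL5 and the glucose-responsive regulator MLXIPL (fry 0.00456; adjusted p = 0.283 with an estimated correlation). In cholesterol synthesis 6 of 20 were higher, 13 adjusted over the list alone, including INSIG1, LSS and CYP51A1 (fry 0.00456; adjusted p = 0.283 with an estimated correlation). Among 14 lipolysis genes 7 were higher, 10 adjusted over the list alone, including LIPE, PDE3B, AQP7 and ADORA1 (fry 0.00484; adjusted p = 0.283 with an estimated correlation). No list call in any comparison held with an estimated correlation.

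Collagen and matrix, myeloid, and T and NK cell genes were also higher in ET backfat. Of 25 collagen and matrix genes 8 were higher, 13 adjusted over the list alone, among them COL3A1 (4871 ± 2814 against 175 ± 135 TPM; log2 fold change 4.98, SE 0.66, adjusted p = 0.00609), SPARC, LUM and the basement membrane collagen COL4A1 (fry 0.0290; adjusted p = 0.436 with an estimated correlation). Of 18 myeloid genes 6 were higher, 16 adjusted over the list alone, led by the neutrophil and monocyte proteins S100A12 (278 ± 184 against 9.87 ± 7.36 TPM), S100A8 and S100A9 and by the macrophage gene CD68 (fry 0.00456; adjusted p = 0.283 with an estimated correlation). Of 9 T and NK cell genes 4 were higher, 7 adjusted over the list alone, namely CD247, GZMA, CD2 and CD3E, the last 3 below 4 TPM in both types (fry 0.00343; adjusted p = 0.283 with an estimated correlation). Of 7 B cell genes only CXCR5 was higher, also adjusted over the list alone (fry 0.132), and the B cell receptor subunit CD79A was at 14.3 TPM in ET and 25.2 in L, a log2 fold change of -0.58 (adjusted p = 0.456). Without the library of S0355 CD79A was lower in ET (-0.999, adjusted p = 0.0212). Of 32 interferon response genes 2 were higher, also adjusted over the list alone (fry 0.296), and of 18 antigen presentation genes 0, or 8 adjusted over the list alone (fry 0.155; camera adjusted p = 0.00510, and adjusted p = 0.822 with an estimated correlation). The haemoglobin entry HBA, from blood in the tissue, was higher with them, at 91.5 ± 73.2 against 5.87 ± 4.75 TPM (log2 fold change 3.75, adjusted p = 0.00758). The haemoglobin entry HBB did not pass in backfat by limma over all genes. ALAS2, the haem synthesis enzyme of red cells, was higher, at 3.72 ± 2.15 against 0.356 ± 0.247. GHR, IGF2R, STC2, IGFBP6, the clock gene PER3 and the opioid precursor PENK (131 ± 122 against 3.33 ± 2.79 TPM) were higher as well. IGFBP6, GHR, IGF2R, CD2, CD3E and ALAS2 lost their calls with median-ratio scaling (adjusted p = 0.0520 to 0.110). None of 34 ribosomal protein genes, 18 slow fibre genes and 19 fast fibre genes passed. By camera the ribosomal protein list lay lower in ET, with a median of -0.55 (adjusted p = 0.436 with an estimated correlation). The fibre lists lay lower in ET by camera, with medians of -2.37 and -2.42 (adjusted p = 0.436 for both with an estimated correlation), and at -0.74 and -0.57 without the library of S0355.

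Without the backfat library of S0355, 911 genes were higher and 126 lower in ET backfat, and 567 of the 574 calls were shared. Of the ribosomal protein genes 17 were then lower (fry adjusted p = 0.00571; adjusted p = 0.250 with an estimated correlation). Median-ratio scaling moved the median over all genes from 0.35 to 0.09 and left 266 calls, 5 of them lower, or 606 higher and 213 lower without that library. The count of 574 became 162 without S0235, 337 without S0242, 237 without S0309, 161 without S0326, 238 without S0377 and 232 without S0384, and 346 of the 574 calls were shared without S0385. The loin library of S0355, which held adipocyte transcripts, was in no backfat fit. Its LEP, at 3.23 TPM, lay above the lowest ET backfat value of 2.92. Its AOC3, at 205 TPM, lay between the L backfat values (7.31 to 35.3) and the ET values (321 to 1018). Its SCD, at 3.86 TPM, lay within the L backfat values of 0.119 to 5.56.

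**Figure D2:**
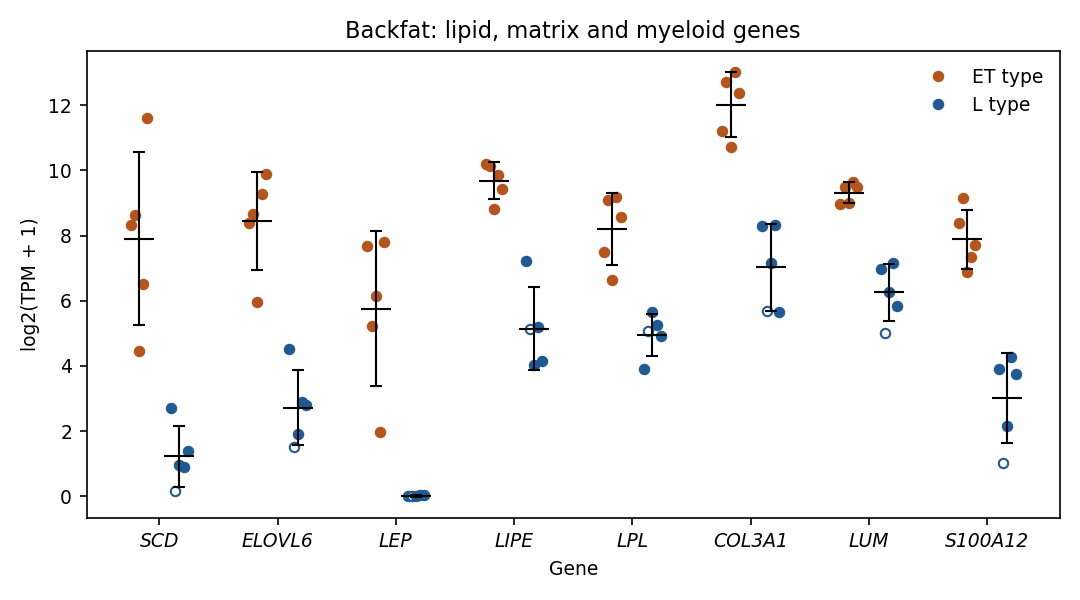
log2(TPM + 1) (y axis) of 8 genes (x axis) in backfat of 5 ET and 5 L animals; points are animals, the open point is the library of S0355, and bars are the mean ± SD per type. For LEP the ET libraries span 2.92 to 220 TPM and the L libraries 0 to 0.0281. The loin library of S0355, which held adipocyte transcripts and had LEP at 3.23 TPM, is not shown.

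In loin, most of the differing genes were lower in ET than in L animals in the TPM as deposited (61 higher and 655 lower), a split that depended on scaling (33 higher and 30 lower with median-ratio scaling, and 1431 and 916 with scaling without the library of S0355). The triglyceride lipase PNPLA2 was at 87.0 ± 22.1 TPM in ET and 302 ± 107 in L (SD, n = 5 each; log2 fold change -1.76, SE 0.28, adjusted p = 0.0183), and LIPE at 13.9 ± 7.02 against 102 ± 97.3 (-2.48, adjusted p = 0.0399). Without the loin library of S0355, which held adipocyte transcripts, LIPE was at 61.2 ± 36.8 TPM in L (n = 4; -2.02, adjusted p = 0.00789). Among the genes lower in ET were the antioxidant enzyme SRXN1 (-2.27), the ferroptosis suppressor AIFM2 (-2.04), IGFBP3 (-3.15), the insulin receptor INSR (-1.32), IGF2R, the glucocorticoid-induced TSC22D3 (-1.42), the clock gene PER1 (-1.35), and CDKN1A (-1.78) and GADD45A (-1.92), which respond to DNA damage. GALNT15, ABAT, DEPP1, CEBPD, GABARAPL1, NET1, PPM1M and TUBB4A were also lower. Higher in ET were the calcium buffer of fast fibres PVALB (69.3 ± 31.4 against 7.84 ± 9.88 TPM; 3.76, adjusted p = 0.0287), the muscle growth inhibitor MSTN (14.4 ± 4.43 against 1.68 ± 2.42; 2.84, adjusted p = 0.0191), NREP, METTL21E, VEGFA (1.13), HBB (2.35), PNCK, MGST2, PI16, RXRG, RAET1E, IQCK and the serine synthesis enzyme PSPH (5.69 ± 1.31 against 0.775 ± 0.863, adjusted p = 0.0178). The L mean of PSPH was 0.402 ± 0.260 TPM without the loin library of S0355 (n = 4). Without that library the log2 fold changes of PVALB, MSTN and IGFBP3 were smaller in size, at 3.19, 2.57 and -2.59. Those of NREP and HBB were larger, at 3.35 and 2.77, and all of these genes still passed. Without S0384 the log2 fold changes of PVALB and METTL21E were 4.35 and 3.50, and without S0385 GALNT15 did not pass (-3.19 from -3.93, adjusted p = 0.0696).

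The 716 genes were called among 11149 tested. Of 19 fast fibre genes only PVALB passed, adjusted over the list alone too (fry adjusted p = 0.799; camera adjusted p = 5.02e-09, and adjusted p = 0.801 with an estimated correlation). Of 25 thyroid, glucocorticoid and circadian genes TSC22D3 and PER1 were lower, also adjusted over the list alone (fry 0.0316; camera 0.690). Of 14 lipolysis genes 2 were lower (fry 0.799), and of 19 growth hormone and IGF genes 3 were lower, 6 lower and 3 higher adjusted over the list alone (fry 0.799, with a median of -0.13 while camera's direction was up). Of 22 hypoxia and redox genes VEGFA was higher and SRXN1, CDKN1A and GADD45A were lower, 1 and 5 adjusted over the list alone (fry 0.0669; 0.0275 without the library of S0355, with 1 higher and 7 lower). Without the loin library of S0355 652 genes were higher and 2659 lower, including all 716 calls, and the fast fibre median went from 2.79 to 0.61. Of 24 collagen and matrix genes 13 were then higher, where none had passed with it (adjusted p = 0.481 with an estimated correlation). With median-ratio scaling, which moved the median over all genes from -0.33 to -0.05, 25 of the named genes lost their calls. Leaving out S0242, S0309, S0326 or S0377 left 0 calls by limma, with 2500, 2418, 2197 and 2477 genes at an unadjusted p under 0.05. Without S0235, S0276 or S0385 there were 137, 88 and 104 calls.

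In tenderloin, matrix genes were higher and a few muscle and lipid genes lower in ET animals. The collagen-binding proteoglycan DCN was at 373 ± 68.1 TPM in ET and 134 ± 14.3 in L (SD, n = 5 each; log2 fold change 1.46, SE 0.16, adjusted p = 0.00800), COL3A1 at 92.6 ± 33.2 against 26.5 ± 12.3 (1.82, adjusted p = 0.0244), and COL1A2 (1.62), LUM (1.43) and COL5A2 (1.11) went with them. Of 22 collagen and matrix genes 5 were higher and 16 adjusted over the list alone (fry adjusted p = 0.0211; camera adjusted p = 1.13e-10, and adjusted p = 0.635 with an estimated correlation). Of 17 antigen presentation genes none passed over all genes and 12 adjusted over the list alone (fry 0.0527; adjusted p = 0.635 with an estimated correlation). Growth-related genes higher in ET were IGF1 (2.66 ± 0.745 against 0.721 ± 0.123 TPM; 1.07, adjusted p = 0.0149), IGFBP4 and IGFBP6, 3 of the 18 in their list and also 3 adjusted over the list alone (fry 0.119). With 1 transcript per gene IGFBP6 was at -0.21. Also higher were NREP, NTMT2, ID1, THY1, CCDC80, ITGB8, STBD1, NPPC, RAET1E, RET, THBS4, CYP51A1, PENK and ASNS.

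The largest differences in tenderloin were in the other direction. The slow-muscle light chain MYL6B was at 87.5 ± 47.3 TPM in ET and 2312 ± 2315 in L (-4.19, SE 0.64, adjusted p = 0.0157), the serine protease PRSS36 at 4.43 ± 2.68 against 70.9 ± 54.3 (-3.59, adjusted p = 0.0129), and the muscle carbonic anhydrase CA3 at 418 ± 124 against 1962 ± 1287 (-2.08, adjusted p = 0.0204). In loin CA3 lay in the other direction, at 1862 TPM in ET and 433 in L, which did not pass with all libraries. Its log2 fold change there was 2.74, or 1.89 without the library of S0355. In backfat the value was 4.93, or 6.50 without the library of S0355 (interaction adjusted p = 0.00405). PNPLA2 was lower as in loin (-1.51, adjusted p = 0.0173), with GPAM (-1.27), HSDL2 (-1.25), the fatty acid oxidation enzyme ACADVL (-0.96), PRSS43, MLLT11, RFLNA, SLC25A22, CEBPD, PROSER2 and RPL5. MYL6B was the sole called member of the 18 slow fibre genes (3 lower and 1 higher adjusted over the list alone). In total 152 genes were higher and 25 lower of 10832 tested. The count was 5 without S0377, 22 without S0326, 85 without S0242, 80 without S0276, 100 without S0309, 75 without S0355, 114 without S0384 and 373 without S0385. MYL6B did not pass without S0326 or without S0377. With all 50 libraries in 1 fit and the animal as a random replicate block 8 genes passed, with MYL6B and without DCN and COL3A1.

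**Figure D3:**
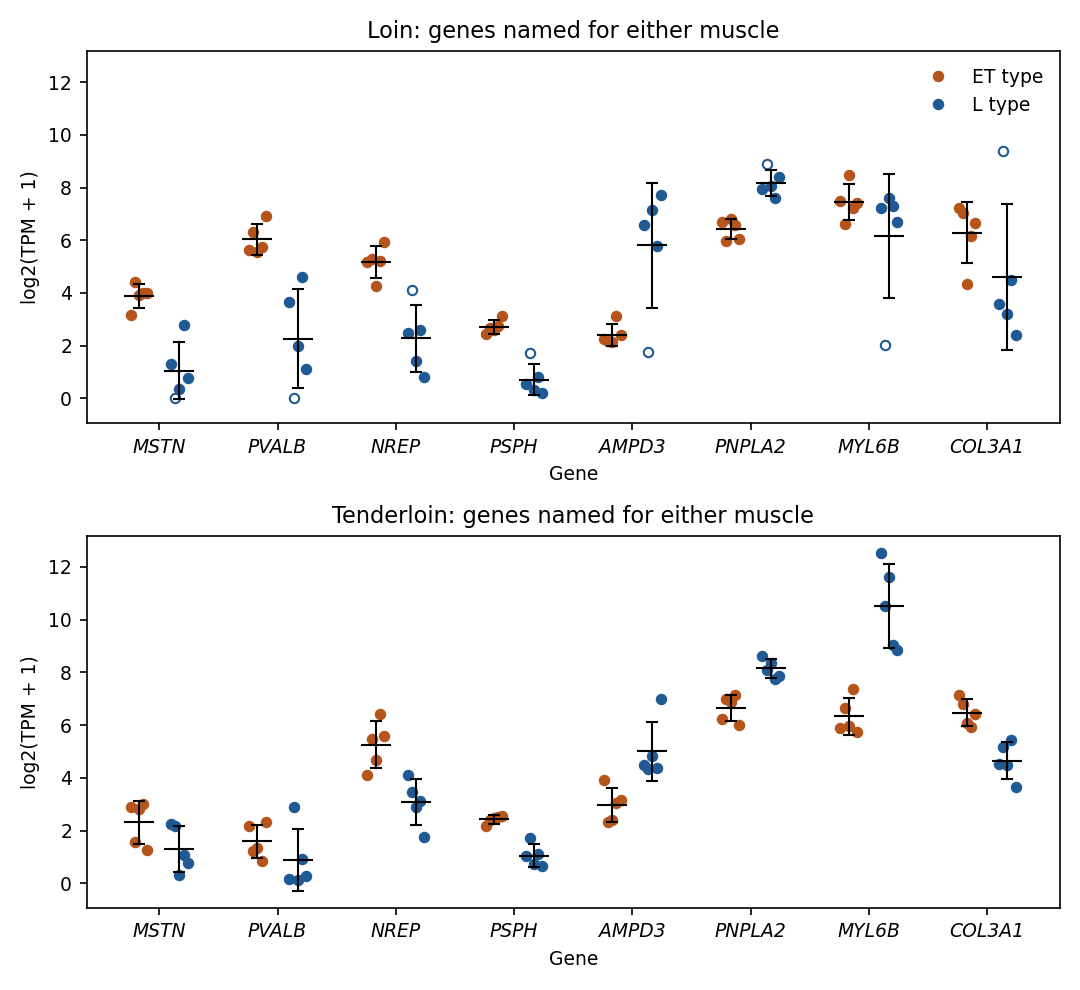
log2(TPM + 1) (y axis) of 8 genes (x axis) in loin (top) and tenderloin (bottom) of 5 ET and 5 L animals; points are animals, the open point is the loin library of S0355, and bars are the mean ± SD per type. PNPLA2 lies lower in every ET library than in every L library of both muscles, and MYL6B in tenderloin only.

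In brain, where most libraries were rich in pituitary hormone transcripts, no gene passed between the types. The potassium channel subunit KCNF1 was at 10.9 ± 4.37 TPM in ET and 2.23 ± 1.44 in L (SD, n = 5 each; log2 fold change 1.95, SE 0.39), C1QL2 at 7.81 ± 6.48 against 1.84 ± 2.22 (1.03 ± 1.47 in L without S0355), and HBB at 116 ± 89.7 against 26.5 ± 20.2. CCDC71 and SPTSSA had log2 fold changes of 0.65 and 0.63. CELSR1, a planar polarity cadherin, was at 10.8 ± 1.32 against 26.3 ± 8.78 TPM (-1.16) and the transcription factor NFIA at 4.74 ± 2.25 against 18.05 ± 7.02 (-1.71). NOD1 (-0.94), KSR1 (-1.03) and PLEKHF1 (-0.92) completed the smallest p in that direction, and PLEKHF1 was at 0.41 with 1 transcript per gene. The adjusted p was 0.841 for all 10 of these genes. By limma 0 of 13179 genes passed, with 500 at an unadjusted p under 0.05, and 0 with 1078 without the brain libraries of S0235 and S0355. No member of any list passed, over all genes or adjusted over the list alone, and by fry 0 of 34 lists passed. Library weights, which lower the weight of libraries far from their group, gave 796 calls, 63 higher and 733 lower.

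In lymph, no gene passed either. The 5 genes of smallest p among those lower in value in ET were all histone entries. H2BC3 was at 2.42 ± 0.447 TPM in ET against 8.52 ± 3.57 in L (SD, n = 5 each; log2 fold change -1.40), H1-2 at 4.78 ± 2.96 against 21.1 ± 13.7 (-1.90) and H2AC25 at 2.97 ± 2.70 against 13.2 ± 5.99 (-2.06), with H3C at -1.32 and H2B1 at -1.08. In the other direction SH3BGR (0.77), a polyubiquitin entry (UBIQP, 0.81), CENPV (200 ± 47.3 against 114 ± 43.6 TPM), SGCA and LXN had the smallest p. The adjusted p was 0.928 for all 10. By limma 0 of 12541 genes passed, with 285 at an unadjusted p under 0.05, and 0 with 526 without the library of S0235. Lymphocyte lists lay lower in ET by camera, with 0 members called over all genes or adjusted over the list alone. The median of 20 B cell genes was -1.62 (adjusted p = 1.31e-07; adjusted p = 0.874 with an estimated correlation). Without the library of S0235, which was low in lymphocyte transcripts, the B cell median was -0.54 and that of 28 T and NK cell genes went from -0.84 (adjusted p = 0.882 with an estimated correlation) to 0.32.

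Averaged over the 5 tissues of each animal, PSPH was the only gene that differed between the types, higher in ET by 1.30 on the log2 scale (SE 0.17, adjusted p = 0.0469), with every ET animal above every L animal. Next to the threshold were AOC3 (1.05), the elongase ELOVL5 (0.92) and RGS14 (0.83), each with an adjusted p of 0.0506, and COL15A1 (1.23, 0.0627), and in the other direction CDKN3 (-0.77, 0.0694), PRSS36 (-1.27, 0.0720), CSRP3 (-1.02, 0.0721), AMPD3 (-1.29, 0.0721) and TMEM145 (-0.81, 0.0866), none of which passed. Adjusted over the list alone, 10 of 18 adipocyte genes, 13 of 22 fatty acid synthesis genes, 10 of 25 matrix genes and 7 of 18 myeloid genes were higher, with 0 over all genes (fry adjusted p = 0.0201, 0.0341, 0.0201 and 0.0201; adjusted p = 0.0784, 0.0893, 0.0784 and 0.0784 with an estimated correlation). Without the animals S0235 and S0355 the fatty acid synthesis list did not pass by fry (adjusted p = 0.1003). At an unadjusted p under 0.05 there were 1769 of 13607 genes. Without the animals S0235 and S0355, 81 genes were higher and 44 lower, PSPH and the 9 genes just listed among them, and with median-ratio scaling 30 passed. Without S0355 alone 68 passed, without S0276 34, without S0235 3 and without S0309 2. PSPH did not pass with a pseudocount of 0.1, with no filter, with 1 transcript per gene, or without S0242, S0309, S0326, S0349, S0377, S0384 or S0385 (adjusted p = 0.0504 to 0.192).

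The size or direction of the type difference depended on tissue for 1103 of 13607 genes. On simulated TPM this test called 64 unchanged genes, so false calls can be more frequent here than the threshold allows. LIPE was 4.54 log2 units higher in ET backfat and 2.48 lower in ET loin (-2.02 without the loin library of S0355), with -1.21 in tenderloin (interaction adjusted p = 1.71e-06). AIFM2 followed it (1.89 in backfat, -2.04 in loin, -1.04 in tenderloin), and LPL was 3.24 higher in ET backfat and at -1.40 in tenderloin. LEP, S100A8, S100A9, SDR16C5, KLB (the co-receptor of FGF21), MCCC2 and ACER3 made up the rest of the 10 genes with the smallest p, all higher in ET backfat, by 2.86 to 6.13. These 10 genes passed in every alternative in which they were tested. Without the 5 libraries that stood apart 3853 genes passed, 1094 of them shared, and with median-ratio scaling 455 passed. The count was 584 without S0242, 445 without S0309, 409 without S0326, 2147 without S0355, 526 without S0377, 705 without S0384 and 602 without S0385.

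Between the muscles, slow fibre and mitochondrial genes were lower in loin than in tenderloin, and the fast myosin MYH4 was higher. MYH4 was at 12253 ± 7029 TPM in loin and 167 ± 161 in tenderloin (SD, n = 10 each; log2 fold change 5.28, SE 1.21, adjusted p = 0.00561), higher than the tenderloin median in 9 of 10 loin libraries and 6.55 higher without the loin library of S0355. IGFN1, MYH8, MICAL2, PFKFB3, SLC7A8, SHISA2, PVALB, AQP3, KCTD16 and the glycolysis enzyme GPI (1.36) were also higher in loin. Lower in loin were MYL3 (-2.95), CSRP3, ANKRD2, MYOZ2, the calcium pump of slow fibres ATP2A2 (-2.14), MYH7B (34.1 ± 25.9 against 210 ± 127 TPM; -2.67, adjusted p = 1.26e-05), CASQ2, TECRL, ABRA, XIRP1 and LDHB. Of 18 slow fibre genes 9 were lower and 17 adjusted over the list alone (fry adjusted p = 0.0233; camera adjusted p = 2.55e-13, and adjusted p = 0.479 with an estimated correlation). Of 19 fast fibre genes 2 were higher, also adjusted over the list alone (fry 0.782; camera 0.931). Of 30 glycolysis and glycogen genes 3 were higher and 2 lower, also adjusted over the list alone (fry 0.569).

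Genes of mitochondria and fat burning followed the slow fibre genes. Of 23 fatty acid oxidation genes 14 were lower in loin, 15 lower and 1 higher adjusted over the list alone, including CPT1B (69.5 ± 23.4 against 198 ± 54.4 TPM; -1.54), ACADVL (-1.64), HADHB and ECI1 (fry adjusted p = 0.00105; adjusted p = 0.215 with an estimated correlation). Of 28 oxidative phosphorylation genes 19 were lower, 27 adjusted over the list alone, including ATP5MC1, COX4I1 and NDUFB5 (fry 0.0233; adjusted p = 0.479 with an estimated correlation). Lipid uptake and storage genes FABP3 (-2.98), LPL (-2.26), GPAM (-1.95) and PLIN5 (-1.96), and VEGFA (-1.85), HBB (-1.49), RCAN2, ZNF385B, FAM240C, DIO2, ATF3, MYC and CCN2 were lower in loin too, while FKBP5 was higher (1.12, adjusted p = 0.0466). Among transcription factor genes, HOXC8 (37.4 ± 19.8 against 1.32 ± 0.736 TPM) and ZIC1 (11.3 ± 9.28 against 0.0769 ± 0.156) were higher in loin, and PITX1 (0.652 ± 2.05 against 15.8 ± 7.41; -3.44, adjusted p = 0.000215) and TBX1 (-3.01) were higher in tenderloin. The loin library of S0235 was an exception, with HOXC8 at 0.490 TPM, ZIC1 at 0.0492 and PITX1 at 6.48, while PITX1 lay at 0 to 0.0373 in the other loin libraries. The tenderloin library of S0349 had PITX1 at 0.0597 TPM.

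With type as a term, 1374 genes were higher and 568 lower in loin of 11073 tested. Without the loin library of S0355 the counts were 2449 and 1675, with 1935 of the calls shared, and 17 of 19 fast fibre genes were higher where 2 had passed (adjusted p = 0.244 with an estimated correlation). Of the 30 glycolysis and glycogen genes 18 were then higher and 6 lower (adjusted p = 0.309 with an estimated correlation). IGFN1 was then at 5.91, MYH8 at 5.23, MICAL2 at 5.05 and SHISA2 at 3.64, and ABRA at -2.63, ANKRD2 at -2.46, XIRP1 at -2.34, CSRP3 at -2.28, MYOZ2 at -2.22 and MYL3 at -2.11. SLC7A8 was at 3.70 without the animal S0355, and IGFN1 at 4.05 without S0349. With median-ratio scaling, which moved the median over all genes from 0.10 to -0.03, 684 were higher and 880 lower, and all named genes kept their direction while FKBP5 lost its call (adjusted p = 0.0874). FKBP5 also lost its call without 9 of the 10 animals in turn, and HBB without 7. The count was 1190 without S0242, 1293 without S0309 and 3991 without S0355. In L animals alone 566 genes passed, 448 of them higher, and MYH4 (3.28, adjusted p = 0.426) and 26 other named genes did not. Without the loin library of S0355, 2167 were higher and 723 lower in L animals, MYH4 passed (5.82, SE 0.59, adjusted p = 0.000261), and 5 named genes did not, namely PVALB, ABRA, XIRP1, ATF3 and MYC. In ET animals alone 564 were higher and 1018 lower.

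**Figure D4:**
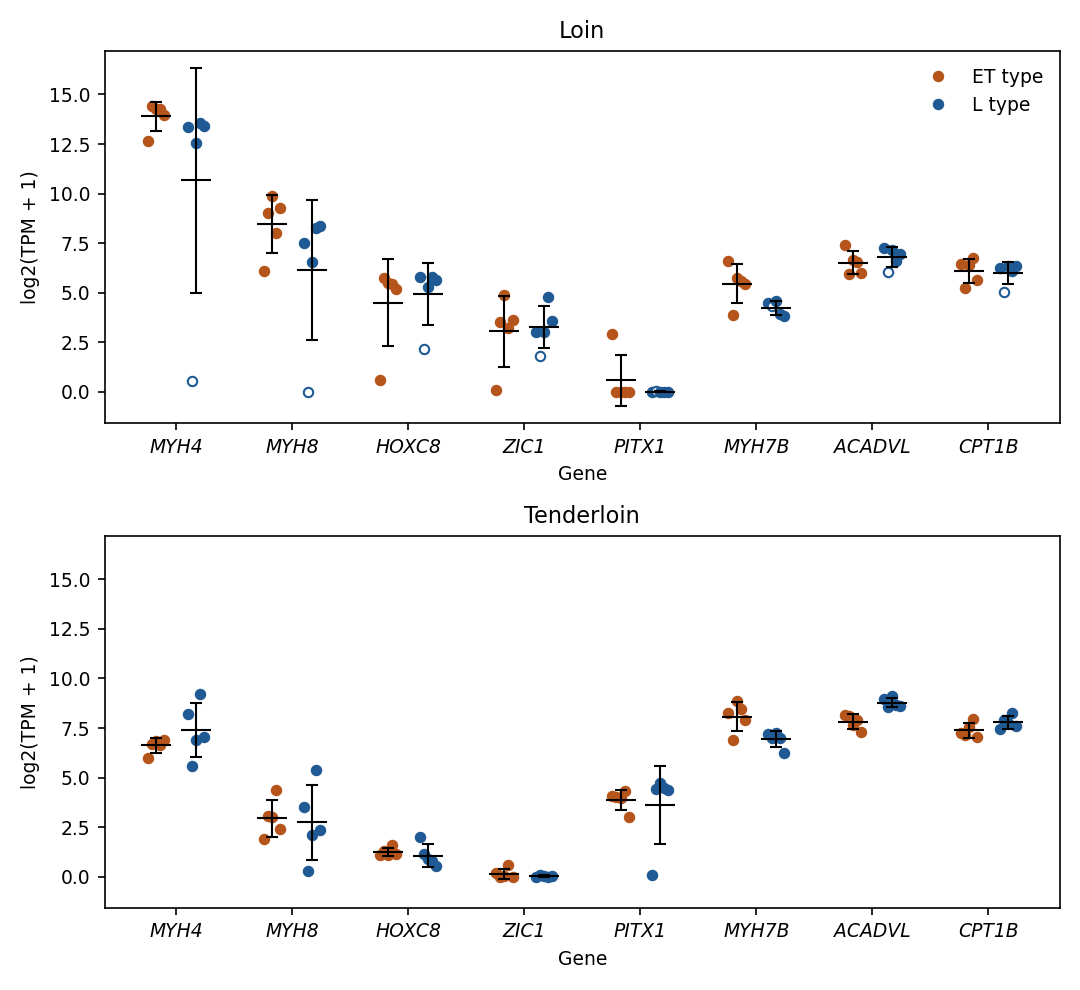
log2(TPM + 1) (y axis) of 8 genes (x axis) in loin (top) and tenderloin (bottom) of 5 ET and 5 L animals; points are animals, the open point is the loin library of S0355, and bars are the mean ± SD per type. MYH4 spans 6385 to 21690 TPM in ET loin and 63.2 to 116 in ET tenderloin; the ET loin point low in HOXC8 and ZIC1 and high in PITX1 is S0235.

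More genes were detected in ET than in L tenderloin, 10845 ± 36.1 against 10460 ± 130 (SD, n = 5 each; exact permutation p = 0.00794, the smallest that 5 against 5 animals can give, adjusted p = 0.0397 over the 5 tissues). In backfat 11907 ± 248 genes were detected in ET and 11217 ± 538 in L (exact p = 0.0159, adjusted p = 0.0397; adjusted p = 0.0595 without S0355). Brain, loin and lymph did not pass, with differences of -259, -137 and -108 genes (adjusted p = 0.344, 0.889 and 0.685 by exact permutation). The difference in loin was 157 genes without the library of S0355. The 10 most abundant genes took 27.2% ± 1.44 of the TPM in ET loin and 22.2% ± 2.12 in L loin (exact permutation p = 0.00794, adjusted p = 0.0397), and the other tissues did not pass (adjusted p = 0.159 to 0.579).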

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

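The interaction test and the scaling alternative were fixed before the data were examined, and the recomputation with transcripts of the L assemblies was set before its result was known. The other tests in this part, and the count over the 42 members after scaling, were chosen after the results were seen.

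The loin library of S0355 had an r of -0.465 with the loin profile (0.830 to 0.935 in the other L loin libraries), 11765 genes detected (10208 to 10461) and 18.3% of its TPM in transcripts without a usable protein match (8.09% to 10.5%). The backfat library of S0355 had an r of -0.464 with the backfat profile (0.610 to 0.854 in the other L backfat libraries). A library of another animal is argued against, since both matched S0355 at 100% of the transcripts that tell the animals apart, and so is a mixture in which each tissue keeps at least 10% of its level, since muscle genes in the loin library were at 0.00411% and fat genes in the backfat library at 7.29% of their level in the other L libraries. The values that an exchange of these 2 libraries needs were there: the loin library correlated with the backfat profile at 0.858, within the 0.610 to 0.866 of backfat libraries, and the backfat library with the loin profile at 0.939, against 0.830 to 0.935. An exchange may therefore be the cause, as a hypothesis found and tested on the same data, and no biological explanation was tested.

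The ET lymph library of S0235 had an r of 0.0306 with the lymph profile (0.947 to 0.971 in the other ET lymph libraries), 19.0% of its TPM in the 10 most abundant genes (13.1% to 14.6%) and 11.95% in mitochondrially encoded transcripts (5.02% to 6.82%). A library of another animal is argued against by an agreement with S0235 of 100%, and a mixture with lymph tissue by 44 lymphocyte genes at a median of 0.792% of their level in the other lymph libraries. All 15 kidney tubule markers, a list written after this library was seen, lay above every other lymph library and summed to 6494 TPM, with UMOD at 2156 and SLC34A1 at 1016. Of the lists for other organs written with it, 4 of 8 liver, 1 of 4 heart, 1 of 6 pituitary, 0 of 3 lung and 0 of 3 spleen markers did so. Kidney tissue in place of lymph tissue is a candidate explanation, and no biological explanation was tested.

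Lipid and matrix genes were higher in ET backfat, with 42 called members of 5 lists at a median log2 fold change of 3.72. Muscle in the L backfat libraries as the cause is argued against by their muscle genes, which outside S0355 reached at most 0.310% of the loin level. Scaling by a few abundant genes is argued against as the whole cause, since 31 of the 42 members were still called after median-ratio scaling, with a median of 3.45 and a lowest value of 1.25. Transcripts assembled from the other type are argued against as the whole cause, for the genes that could be measured with L assemblies. Of the 573 genes higher in ET, 393 had transcripts of L assemblies at a mean TPM of at least 1. With these transcripts alone 171 of the 393 were called higher, and their median was 1.72 against 1.93 with all transcripts. Of the 42 members 31 were measured in this way, and 22 were called higher. The genes not measured in this way could not be tested, and the explanation stays open for them. A difference between the types in the amount or state of fat cells may remain, and it was not tested apart from other differences between these animals.

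The ET brain library of S0235 had 11979 genes detected (12757 to 12986 in the other ET brain libraries), 31.4% of its TPM in mitochondrially encoded transcripts (4.37% to 11.9%) and an r of 0.459 with the brain profile (0.815 to 0.958). Of 50 pairs of a group and a library measure, 10 held a library far from the other 4, against about 5% by chance, and these came from 4 libraries. The type difference depended on tissue for 1103 genes in the interaction test. Transcripts with no usable protein match, which entered no comparison, took a median of 13.03% of the TPM.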

How the results depend on the processing

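Settings that leave out chosen libraries or named pairs of animals, alone, with scaling or in 1 type, were chosen after seeing the data, and the others before the data were examined. Causes were not tested except where fewer libraries or genes are named. Depth cannot be read from TPM, so the spread between animals and the few animals per type limit the precision.

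Of the named values, 225 of 231 kept their direction and side of the threshold with a pseudocount of 0.1, 187 of 231 with median-ratio scaling, 156 of 206 with 1 transcript per gene, 179 of 206 with no filter and 182 of 187 with a mean TPM of at least 5. The same held for 89 of 137 with a random replicate block, 124 of 139 with library weights, 88 of 92 without the 5 libraries that stood apart, and 1580 of 2058 values with 1 animal left out. The values that changed sign were PLEKHF1 in brain (0.41) and IGFBP6 in tenderloin (-0.21) with 1 transcript per gene, and the genes detected in loin, at 25.6 with a TPM of at least 0.1 and 156.8 without the library of S0355, against -137.

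In backfat, 574 genes became 266 with median-ratio scaling, 1722 with all 50 libraries in 1 fit and a random replicate block, and 2498 with library weights, where 573 of the calls were shared. Leaving out 1 animal gave 161 to 1037. In loin, 716 became 63 with scaling, 283 with 1 transcript per gene, 3712 with library weights, 2347 with scaling without the library of S0355, and 2901 without the loin libraries of S0355 and S0235. Leaving out 1 animal gave 0 to 3311, the 0 by limma with 2197 to 2500 genes at an unadjusted p under 0.05. In tenderloin, 177 became 93 with a mean TPM of at least 5, 51 with 1 transcript per gene, 8 with a random replicate block (7 shared) and 689 with library weights. Leaving out 1 animal gave 5 (without S0377) to 373 (without S0385).

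In brain, the 0 by limma became 1 with a random replicate block, 796 with library weights, and 1 without the libraries of S0235, S0355, S0326 and S0384. It stayed 0 with 1 animal left out (260 to 828 genes at an unadjusted p under 0.05). In lymph, the 0 became 3 with a random replicate block and stayed 0 with library weights (1104 at an unadjusted p under 0.05) and with 1 animal left out (133 to 843). In the mean over tissues, 1 gene became 0 by limma with no filter (1830 at an unadjusted p under 0.05) and with 1 transcript per gene (1625), 3 with a mean TPM of at least 5, 30 with scaling and 125 without the animals S0235 and S0355. Leaving out 1 animal gave 0 to 68, the 0 without S0242, S0326, S0349 or S0377 (1195 to 1598 at an unadjusted p under 0.05).

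The 1103 genes whose type difference depended on tissue became 455 with scaling, 3853 without the 5 libraries that stood apart, and 409 to 2147 with 1 animal left out. Without the replicate block there were 1006. Between loin and tenderloin, 1942 became 566 in L animals alone (2890 there without the loin library of S0355), 4124 without the 5 libraries that stood apart, 4265 with scaling without the loin library of S0355, 4216 without the loin libraries of S0355 and S0235, and 1190 to 3991 with 1 animal left out. With the animal as a replicate block there were 1597 (1025 higher and 572 lower). Among the named genes that block ended the enrichment of MYL2 and MYL3 in tenderloin, and changed no other call.

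Genes enriched in loin went from 8 to 17 without the 5 libraries that stood apart. Those enriched in tenderloin went from 23 to 15 without them, 40 with a pseudocount of 0.1 and 43 with scaling. The number of tissues whose detected genes differed went from 2 to 1 with a TPM of at least 0.1 and to 1 without the 5 libraries that stood apart. Of 228 list tests, 72 passed by camera, 0 with an estimated correlation and 21 by fry, 15 of them shared. Without the 5 libraries that stood apart 80 passed by camera, 46 of the 72 in the same direction and 2 in the other. Those were oxidative phosphorylation in backfat (median 0.15 while camera's direction was down, then 0.66 and up, adjusted p = 0.00985, or adjusted p = 0.815 with an estimated correlation) and T and NK cells in lymph (-0.84, then 0.32 and up, adjusted p = 1.32e-08, or adjusted p = 0.960 with an estimated correlation). The planned covariate from XIST was not run, because no transcript was matched to XIST.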

Other observations

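The values and tests in this part were chosen after the results were seen, apart from the counts that the splits test and the limma values over all libraries, which come from fits set before the data were examined.

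Haemoglobin HBB was picked after its differences were seen, and its p-values are adjusted over the 5 tissues alone. By limma over all genes it passed in loin (adjusted p = 0.0445) and not in backfat (0.0646), brain (0.841), lymph (0.928) or tenderloin (0.154). It was at 146 ± 155 TPM in ET and 23.1 ± 23.6 in L backfat (SD, n = 5 each; exact permutation p = 0.00794, adjusted p = 0.0198), at 16.6 ± 24.7 against 2.41 ± 1.22 in lymph (exact p = 0.00794, adjusted p = 0.0198), at 40.7 ± 17.8 against 9.06 ± 8.39 in loin (exact p = 0.0159, adjusted p = 0.0265) and at 116 ± 89.7 against 26.5 ± 20.2 in brain (exact p = 0.0317, adjusted p = 0.0397). Tenderloin did not pass, at 131 ± 118 against 30.7 ± 26.1 (exact p = 0.0714). Without the library of S0235 the ET mean in lymph was 5.56 ± 1.89 (n = 4; exact p = 0.0238, adjusted p = 0.0397), and without that of S0355 the L mean in loin was 5.68 ± 4.23 (n = 4). Without the libraries that stood apart brain did not pass either (exact p = 0.0857). Replication-dependent histones, summed over 16 entries, were at 310.1 ± 90.2 TPM in ET and 609 ± 206 in L lymph, which did not pass (exact p = 0.0238, adjusted p = 0.119; adjusted p = 0.0794 without the library of S0235). POMC, far below its brain level, was at 1.94 ± 0.345 TPM in ET and 5.20 ± 0.647 in L loin (exact p = 0.00794, adjusted p = 0.0397).

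AMPD3, the AMP deaminase 3 gene, was at 2.38 TPM in the loin library of S0355 and at 54.0 to 212 in the other L loin libraries, against 3.35 to 7.74 in ET loin. By limma the log2 fold change in loin was -3.39 (adjusted p = 0.0571), and -4.40 without that library (adjusted p = 0.000178). In tenderloin it was at 19.1 to 126 TPM in L and 4.02 to 14.1 in ET, which did not pass (-2.04, adjusted p = 0.0574). The ET loin library of S0235 was low in HOXC8 (0.490 TPM against 35.5 to 52.2 in the other ET loin libraries) and in ZIC1 (0.0492 against 8.32 to 28.7) and had PITX1 at 6.48 TPM, which was listed at 0 in the others. Among the L tenderloin libraries PITX1 spanned 0.0597 to 25.4 TPM. The pituitary hormone gene PRL was at 805 to 40120 TPM in the brain libraries other than those of S0235 and S0355 (11.09 and 13.98), CGA at 2085 to 28265 (0.737 and 4.46) and POMC at 5271 to 77972 (6.92 and 7.75). GFAP, an astrocyte gene, was at 5001 and 15095 TPM in the libraries of S0235 and S0355 against 0.985 to 43.6 in the others. Of the sex-linked list 3 genes were matched. Mean TPM over 25 libraries was 13.1 in ET and 16.9 in L for KDM5D, 2.08 and 2.43 for ZFY, and 9.79 and 8.26 for USP9Y. USP9Y spanned 0 to 38.3 TPM in ET and 0 to 29.9 in L. The highest identity of a transcript to its entry was 90.1% for KDM5D, 87.1% for ZFY and 97.2% for USP9Y. These means mix tissues, an entry can hold a related gene, and no sex was read from them.

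Other splits of the animals were drawn, 100 for each result with the real one included. The real split gave the most calls in backfat (574 genes, highest other split 80, 1 of 100 as large). The same held in loin (716, highest other 4, 1 of 100) and tenderloin (177, highest other 5, 1 of 100). It held too for the interaction (1103, highest other 866 with S0276 and S0355 exchanged, 1 of 100). For the lists by fry the real split gave 16 (highest other 6, 1 of 100). A chance split is argued against by these ranks, but 100 splits cannot exclude it. The backfat and loin fits keep the libraries of S0355, and the interaction test called too many unchanged genes on simulated TPM. Other splits more often gave as many for the mean over tissues (1, highest other 3, 6 of 100) and the lists by camera (66, highest other 86, 60 of 100). In brain and lymph all 100 splits gave as many as the 0 by limma (500 and 285 genes at an unadjusted p under 0.05). The highest other in brain, 123, put S0235, S0276, S0326, S0355 and S0384 together, which points to a structure of these samples, and the highest other in lymph was 1.

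Without the library of S0355, the real split gave the most calls in loin (3311, highest other 609, 1 of 100), and in backfat 2 of 100 splits gave at least the real 1037. The highest other split in backfat, 1102, put S0276 with the L animals and gave more calls than the real types. The test thus does not tell the type apart from another structure of these samples there. Without the library of S0235, all 100 splits gave as many as the 0 in lymph by limma (526 genes at an unadjusted p under 0.05; highest other 2). With the muscles exchanged within animals, no other split gave as many for loin against tenderloin (1942, highest other 1631, 1 of 100). The same held without S0355 (3991, highest other 3568, 1 of 100). In both, the highest other split differed from the real one in S0235 alone, and the median of the other splits was 0. An exchange puts unlike muscles in 1 group, which by itself lowers the count, so no conclusion on chance is drawn here either. With tissue labels permuted within animals, no other split gave as many enriched genes in 4 tissues, each 1 of 100. These were backfat (173, highest other 0), brain (1104, highest other 0), lymph (619, highest other 0) and tenderloin (23, highest other 22). A permuted label mixes libraries of unlike tissues, and the median of the other splits was 0 in every tissue. The low counts thus follow largely from the permutation itself, and no conclusion on chance is drawn from them. In loin (8, 2 of 100) a single split gave 204, many more than the real labels, which points to a structure of the samples.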
